A study of Mus musculus with 6 samples.

How the data were processed

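The series holds RNA sequencing of hearts from 6 C57BL/6 mice, 3 wild-type and 3 Trdn-as knockout, with replicates 1 and 2 of each genotype taken at 14 months and replicate 3 at 5 months per the labels. Per the labels' protocols, RNA was extracted with Trizol and Illumina libraries were made from 1 ug of total RNA by BGI. Per the submitters' processing notes, reads were quantified with Salmon 1.5.2 against mm10; the further settings and the normalization step are not given in the sources used here. The values deposited by the authors are a normalized gene-level signal and not whole reads. This was read from the values: they are not whole numbers, and in every library the median over genes of the ratio to the geometric mean of the 6 libraries is close to 1. In the low range 8.42 to 11.8% of values lay at whole multiples of a common step (tolerance 0.01), so whole reads could not be recovered. The depth implied by the smallest steps in units of 1e6 reads was 22.6, 22.3 and 19.1 in WT and 23.0, 22.3 and 19.0 in KO. This leaves low values such as those of Gm47845 with counting error of their own. Genes above 0 numbered 17543, 17619 and 16735 in WT and 17722, 17642 and 17417 in KO.

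Of the gene identifiers 20122 were matched to GENCODE M21 (GRCm38, the same build as mm10) for symbols, positions and types, 132 were unmatched, and 108 broken lines without values were left out. The 20254 genes took in 17478 protein-coding genes and 1939 processed pseudogenes, and 214 were at 0 in every library. No libraries were duplicates: at most 5.27% of genes lay within 1% of each other in any 2 libraries.

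The design was written before the data were examined, with a count-based quasi-likelihood test as the planned method. Because the values are not counts, that test was changed to limma 3.58.1 in R 4.3.3. It fits a linear model on log2(value + 1) with moderated variances (trend and robust options). Genes at a value of 10 or more in at least 3 libraries were kept (13823 tested, 6431 left out), with Benjamini-Hochberg adjustment and a threshold of 0.05. A second planned tool, a count-based Wald test, was not run for the same reason; limma-voom was run on the values as a rough alternative. KO was compared with WT with age as a covariate (3 residual degrees of freedom), 5 with 14 months with genotype as a covariate, and the interaction of genotype and age in a further model (2 residual degrees of freedom). For Trdn an exact permutation test of the 6 libraries and an exact sign-flip test of the same-number differences stand beside the fit. Fold changes are differences of log2 values, SE is the limma standard error with moderated variance, and SD is over the values of a group.

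Replicate numbers are shared by a WT and a KO library in the titles per the labels, which state no litter or pairing. Correlations of same-number libraries after removal of the gene mean were 0.390, 0.383 and 0.617, but cross pairs at 14 months reached 0.369 and 0.382. Pairs of different age lay between −0.4756 and −0.489. After removal of the mean of the 14-month libraries the same-number value was 0.0147 (−0.0503 without Y-linked genes). The pairing was therefore kept as an alternative, a replicate block with 2 residual degrees of freedom. As sex follows the replicate number, a sex term in the genotype test is the same model as the block.

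The 34 gene lists were fixed with the design: calcium release unit, calcium uptake and extrusion, cardiac stress and fetal genes, sarcomere, ion channels and conduction, SR proteins and muscle splicing regulators, beta-adrenergic signalling, fatty acid oxidation, nuclear oxidative phosphorylation, mitochondrially encoded genes and glucose use. Further lists were integrated stress response, unfolded protein and heat shock response, extracellular matrix, interferon response and cell cycle. Cell and tissue lists were macrophage, lymphocyte, neutrophil, endothelial, fibroblast, smooth muscle and pericyte, adipocyte, epicardial and mesothelial, Schwann cell, erythroid, atrial, skeletal muscle, lung and thymus. The last were circadian clock, immediate early genes, glucocorticoid and fasting response, and sex-linked genes. Lists with 5 or more tested members (31) were tested with camera of limma at an inter-gene correlation of 0.01, adjusted over the lists; camera with a correlation estimated per list and the rotation test fry stand beside it. Neutrophil (4 tested members, values up to 110), lung (2, up to 5283) and thymus (2, up to 68.2) were too small. Members were counted at adjusted p under 0.05 over all genes and adjusted over the list alone.

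Named genes followed a rule fixed with the design: Trdn and genes annotated at its locus; genes of largest fold change at adjusted p under 0.05, or the 10 of smallest p where fewer than 5 passed; and up to 4 called members of each list. It also took the 3 most abundant members of the calcium, stress and splicing lists; up to 6 higher and 6 lower genes by age; 4 genes of the interaction; and the most abundant member of the sex-linked, circadian, erythroid, atrial, skeletal muscle and lung lists. Predicted genes and pseudogenes are described only as such. Shared sequence was counted as words of 31 bases in the GENCODE M21 transcripts. Genes within 1 Mb of Trdn were listed as its neighbours.

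Alternatives tried were median-of-ratios, upper-quartile, total and quantile scaling, limma-voom, no filter and a filter of 1 per 1e6 (CPM) in 3 libraries, removal of mitochondrial and haemoglobin genes, a threshold of 0.10, pseudocounts of 0.5 and 10, and removal of pseudogenes. Models were also run with removal of each library's trend with transcript length and GC content, no age term, no genotype term, a sex term, the replicate block, the 14-month libraries alone and each library left out in turn. P-values measure only the spread among these 6 samples.

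The procedure was tested on simulated data with 100 genes planted at each size, drawn from the more abundant genes. For KO against WT, log2 changes of 0.7, 1, 2 and 3 were recovered in 21, 74, 99 and 100 of 100 genes, and for 5 against 14 months changes of 1 and 2 in 66 and 100 of 100. False calls were at most 7 among 13707 genes. Changes of 0.7 and 3 were planted together, as were 1 and 2, so the larger ones eased the adjusted threshold for the smaller. Recovery of the smaller changes may therefore be lower in the real KO against WT comparison, where no gene passed. In simulated noise that was independent between genes, a list planted with a shift of 0.5 was the 1 list called. As genes of a list are correlated in real hearts, this cannot show how often camera calls lists falsely there.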

Results

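Hearts of 6 adult C57BL/6 mice were compared, 3 wild-type (WT) and 3 labelled as knockout (KO) of Trdn-as, a long non-coding RNA whose name places it antisense to the triadin gene Trdn. In each genotype, replicates 1 and 2 came from 14 months of age and replicate 3 from 5 months. The normalized totals, in units of 1e6, were 20.8, 19.9 and 23.5 in WT and 21.6, 20.4 and 19.8 in KO. Mitochondrially encoded genes took 45.6, 44.3 and 40.0% in WT and 49.4, 45.0 and 41.6% in KO. The table listed 20254 genes, and 13823 of them reached a value of 10 in 3 or more libraries and were tested.

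The Y-linked genes added up to 2854, 54.9 and 3895 in WT and 2496, 82.2 and 4482 in KO. Replicates 1 and 3 therefore read as male and replicate 2 as female in both genotypes. Libraries of the same age had Spearman correlations of 0.967 to 0.987 over genes, against 0.932 to 0.945 between ages. The first principal component (59.0% of the variance) parted 5 from 14 months. Age was a covariate in the limma fit of genotype, as fixed with the design from the labels, save in the alternatives that left it out.

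**Figure D1:**
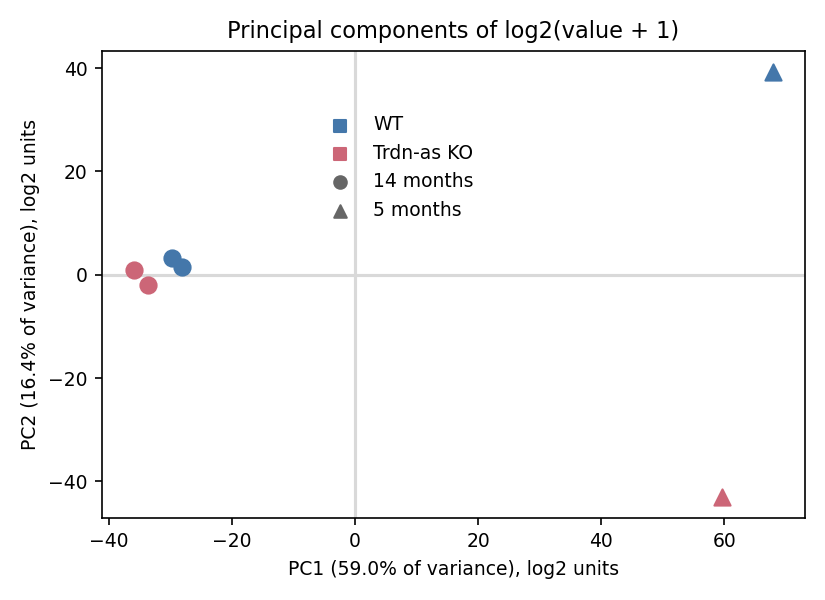
First and second principal components of the log2 values of the tested genes, with 1 point for each of the 6 libraries, colour for genotype and shape for age. The first axis parts the 5-month from the 14-month hearts.

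Trdn, which encodes triadin, a protein of the junctional sarcoplasmic reticulum that links calsequestrin to the ryanodine receptor, stood lower in KO than in WT in every replicate. Its values were 5702, 5600 and 9104 in WT (mean 6802, SD 1994, n = 3) and 3429, 3460 and 5606 in KO (mean 4165, SD 1248, n = 3). The KO library held 60.1, 61.8 and 61.6% of the WT value of the same replicate number. The fitted level was 61.2% of WT (95% interval 51.9 to 72.1%), a log2 fold change of −0.71 (SE 0.10). Over all genes tested Trdn did not pass the threshold (limma adjusted p = 0.261), while it passed among the members of the calcium release list (limma adjusted p = 0.00336 adjusted over the list alone). An exact permutation test of the 6 libraries gave p = 0.2, where 0.1 is the smallest it can give. That test ignores age, and Trdn also differed between the ages (0.70 log2, SE 0.11), so it cannot judge the genotype difference apart from age. An exact sign-flip test of the same-number differences (−0.73, −0.69 and −0.70 log2) gave p = 0.25, the smallest it can give. In the 4 libraries of 14 months alone the limma estimate was −0.71 with an adjusted p = 0.0476, and over all alternatives the adjusted p ran from 0.0476 to 1.00. The genotype difference of Trdn at 5 months minus that at 14 months was 0.01 log2 (SE 0.13, limma adjusted p = 0.961).

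**Figure D2:**
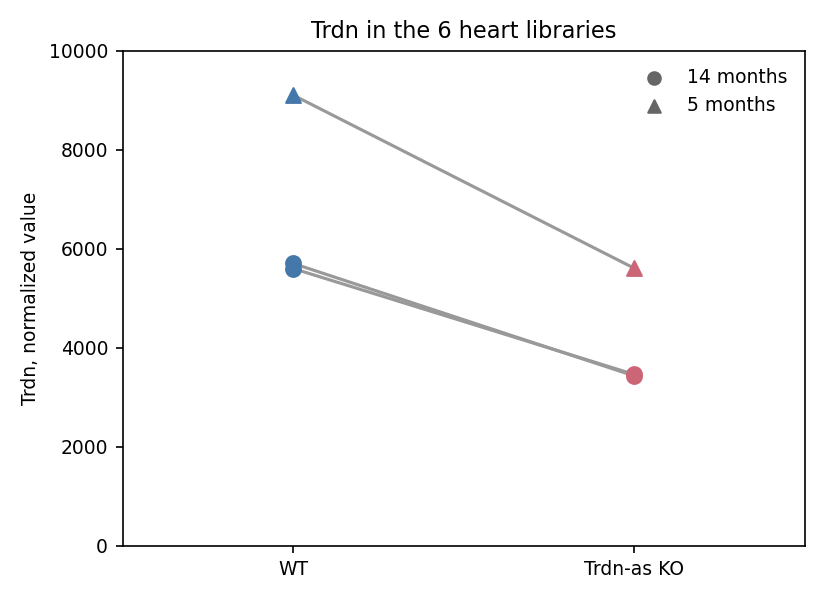
Normalized value of Trdn in each of the 6 libraries, where lines join the WT and KO library of the same replicate number, circles are 14 months and triangles 5 months. All 3 lines descend from WT to KO.

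Trdn lies on chromosome 10 (33080554 to 33476709, plus strand, mm10). An antisense gene annotated within it, D830005E20Rik (33222345 to 33256418, minus strand), was not analysed here, so the loss of Trdn-as itself was not checked in these libraries. Gm47845, a processed pseudogene annotated within Trdn on the plus strand (33211085 to 33211632), had values of 31.3, 25.4 and 15.0 in WT and 2.94, 2.79 and 5.64 in KO, a log2 fold change of −2.37 (SE 0.50, n = 3 per genotype, limma adjusted p = 0.745). Gm47842, a processed pseudogene within Trdn on the minus strand, differed by −0.04 log2 (SE 0.37, limma adjusted p = 0.979). Its differences were −0.58, −0.55 and 1.02 in replicates 1, 2 and 3. Gm47844, also within Trdn, did not pass the filter. Of 19 genes of the table within 1 Mb, 10 were tested and 0 passed by limma. In this region 2 genes had an unadjusted p under 0.05, Trdn and Gm47845. limma-voom called 0 of all genes.

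No gene passed an adjusted p of 0.05 between KO and WT over the whole table. limma called 0 genes with a smallest adjusted p of 0.226, and limma-voom called 0. In all, 841 genes had an unadjusted limma p under 0.05, where 691 would be reached by chance. In 398 genes (2.88%) all KO libraries lay above all WT libraries and in 400 (2.89%) below. For libraries that differ in nothing else, 10% of genes would do so by chance, both sides together. As each genotype holds both ages, genes that differ by age part the genotypes less often, so these shares cannot be compared with that figure. The genes of smallest p, none of them past the threshold, were led by Rnf144b, which encodes an E3 ubiquitin ligase (chromosome 13, 47122656 to 47247991). It had a mean of 676 (SD 62.6) in WT and 331 (SD 27.2) in KO and a log2 fold change of −1.03 (SE 0.11, limma adjusted p = 0.226). Fkbp5, a co-chaperone of the glucocorticoid receptor and a target of it (chromosome 17, 28399094 to 28517527), averaged 599.7 (SD 21.04) in WT and 320.3 (SD 36.7) in KO, a log2 fold change of −0.91 (SE 0.13, limma adjusted p = 0.261). Zbtb16, a zinc finger transcription factor also induced by glucocorticoids (chromosome 9, 48654297 to 48836222), averaged 1335 (SD 79.3) against 472 (SD 231), −1.61 log2 (SE 0.26, limma adjusted p = 0.300). Fam117b (chromosome 1, 59913006 to 59985346) averaged 869 against 423, −1.09 log2 (SE 0.17, limma adjusted p = 0.300). Clcn1, the chloride channel of skeletal muscle membranes (chromosome 6, 42286685 to 42315756), stood higher in KO, at 106 (SD 11.8) in WT and 247 (SD 61.8) in KO, 1.19 log2 (SE 0.19, limma adjusted p = 0.300). The remaining places of the 10 went to the predicted genes Gm10801 (1.41), Gm10721 (1.20) and Gm10800 (1.49), which share 35.8 to 89.3% of their 31-base words with other predicted genes of this kind. The last was the predicted gene Gm49358, listed at 0 in all WT libraries and at 23.1, 15.3 and 53.0 in KO.

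**Figure D3:**
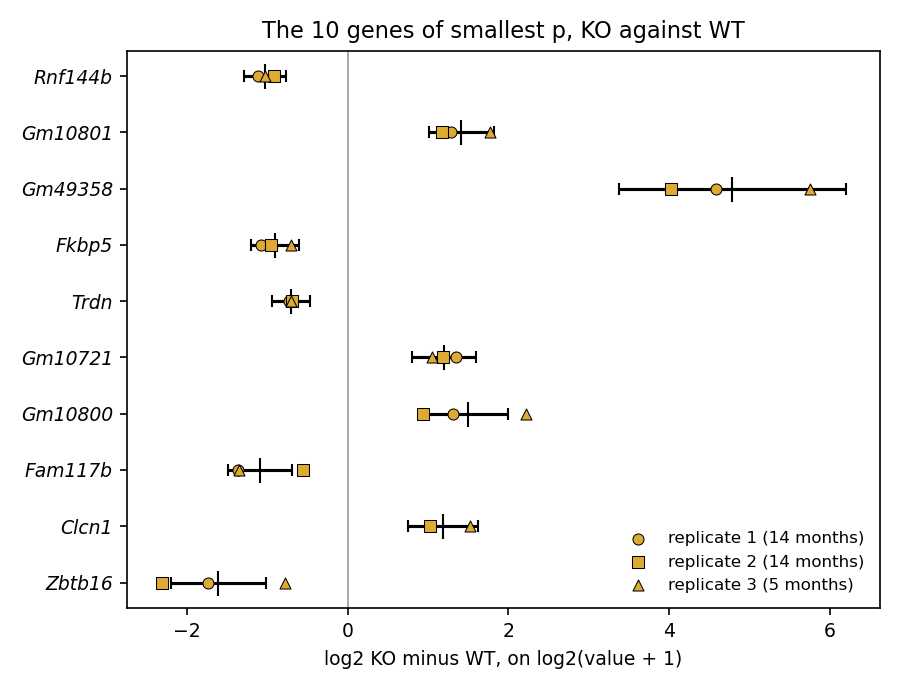
Log2 KO minus WT in each replicate (circle 1, square 2, triangle 3) for the 10 genes of smallest p, with the limma estimate as a black tick and its 95% interval as a line. None of these genes passed an adjusted p of 0.05.

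Within the 14-month hearts (n = 2 per genotype), a smaller set of libraries taken up as an alternative, 14 genes passed by limma, 7 higher and 7 lower in KO. Besides Trdn they took in Zbtb16 (−2.03) and Rnf144b (−1.02) among the lower genes. Gpd1, a glycerol-3-phosphate dehydrogenase of the cytosol (1.40), and Tmem45b (2.63) were among the higher ones. In the 5-month pair Gpd1 stood at 0.11 and Tmem45b at −0.86, while Zbtb16 (−0.77) and Rnf144b (−1.03) were lower there too. Vcp-rs, Gm10039, Gm45140 and Gm20708 were listed at 0 in KO-1 and KO-2, and Gm10801, Gm10800, Gm10721, Gm10719 and Gm10718 are predicted genes. These genes beyond the 10 above were named after their values were seen.

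Among the genes of the calcium release unit, Ryr2, the ryanodine receptor, differed by −0.07 log2 (SE 0.11), Casq2, the calcium buffer of the sarcoplasmic reticulum, by −0.05 (SE 0.11) and Cmya5 by 0.08 (SE 0.13; n = 3 per genotype). Hrc, the histidine-rich calcium-binding protein that binds triadin, stood at −0.37 (SE 0.21), with −0.08, 0.08 and −1.10 in replicates 1, 2 and 3, and was named after its values were seen. The calcium release list had 13 members above and 15 below WT, with a median of −0.04 (camera adjusted p = 0.434). It held 0 members called over all genes and 1 adjusted over the list alone, Trdn, and its median changed sign under quantile normalization. Among the genes of calcium uptake and extrusion, the calcium pump Atp2a2 differed by −0.04 (SE 0.14), its inhibitor Pln by −0.05 (SE 0.13) and Vdac1 by −0.23 (SE 0.15), and the list median was 0.02 (camera adjusted p = 0.755). The regulators of splicing and SR proteins had a median of −0.01 and a mean of 0.01 (camera direction up, adjusted p = 0.563). Among them Qk was at 0.16 (SE 0.13), Hnrnpu at 0.09 (SE 0.13) and Mbnl2 at −0.03 (SE 0.10). For these 2 lists the count was 0 over all genes and 0 adjusted over the list alone.

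The stress and fetal genes were mostly below WT, 18 of 27, with a median of −0.22 (camera adjusted p = 0.0343, and adjusted p = 0.598 with an estimated correlation). Nppa, the atrial natriuretic peptide, stood at −0.47 (SE 0.24), Fhl2 at −0.24 (SE 0.18) and Ankrd1 at 0.21 (SE 0.14). Sarcomere genes were below WT in 25 of 31 members, median −0.24 (camera adjusted p = 0.00105, and adjusted p = 0.598 with an estimated correlation). Their medians were −0.07, 0.08 and −0.56 in replicates 1, 2 and 3. Nuclear genes of oxidative phosphorylation were below WT in 45 of 45 members by a median of −0.20 (camera adjusted p = 1.80e-09, and adjusted p = 0.598 with an estimated correlation). The replicate medians were −0.07, −0.02 and −0.51. Fatty acid oxidation was below WT in 26 of 32 members, median −0.11 (camera adjusted p = 0.0161, and adjusted p = 0.598 with an estimated correlation). Glucose use was below in 20 of 24, median −0.20 (camera adjusted p = 0.00105, and adjusted p = 0.598 with an estimated correlation), at −0.11, 0.07 and −0.60 in the replicates. None of these lists held a gene called over all genes or adjusted over the list alone. All 5 lost their call in the 14-month hearts alone, with medians of −0.17, −0.04, −0.02, −0.04 and −0.01 in the order given.

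Matrix and proliferation lists had negative medians, without a gene past the threshold over all genes. Extracellular matrix genes were below WT in 33 of 36 members, median −0.28 (camera adjusted p = 1.60e-07, and adjusted p = 0.598 with an estimated correlation). Replicates 1, 2 and 3 stood at −0.03, −0.17 and −0.65, and at 14 months alone the median was −0.11 with the call kept. Examples are Col3a1 at −0.60 (SE 0.21) and Col1a1 at −0.37 (SE 0.17), named after their values were seen. Fibroblast markers had a median of −0.24 with 16 of 18 below (camera adjusted p = 0.00178, and adjusted p = 0.598 with an estimated correlation), at 0.17, −0.17 and −0.69 in the replicates. Cell cycle genes had the largest median among the lists with the same sign in all 3 replicates, −0.53 with 19 of 20 below (camera adjusted p = 2.86e-07, and adjusted p = 0.279 with an estimated correlation). The replicates stood at −0.84, −0.48 and −0.79. In that list 0 genes passed over all genes and 3 when adjusted over the list alone: Mki67, the proliferation marker, at −1.08 (SE 0.23), the mitotic kinase Cdk1 at −1.39 (SE 0.35) and the spindle checkpoint kinase Bub1 at −2.14 (SE 0.59). Endothelial markers had a median of −0.14 with 16 of 18 below (camera adjusted p = 0.00466, and adjusted p = 0.598 with an estimated correlation). Macrophage markers had a median of −0.18 with 17 of 23 below (camera adjusted p = 0.0437, and adjusted p = 0.674 with an estimated correlation). Replicate 1 was on the other side for endothelial (0.07) and macrophage markers (0.08). The fibroblast and macrophage calls were lost at 14 months alone (medians −0.00 and −0.05).

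The immediate early genes, which respond within minutes to stimuli, were above WT in 18 of 24 members, median 0.27 (camera adjusted p = 7.99e-06, and adjusted p = 0.598 with an estimated correlation). No member passed over all genes, and 8 passed when adjusted over the list alone: Nr4a1 2.04, Nr4a3 1.67, Fosb 1.47, Nr4a2 1.32, Fos 1.13, Fosl2 0.91, Btg2 0.47 and Ier3 −0.69. Adipocyte markers had a median of 0.73 with 14 of 15 above (camera adjusted p = 2.77e-05, and adjusted p = 0.598 with an estimated correlation). Their medians were 1.65, 2.10 and −1.04 in replicates 1, 2 and 3, and at 14 months alone the median was 1.66. Ion channels had a median of 0.10 with 25 of 38 above (camera adjusted p = 0.0171, and adjusted p = 0.417 with an estimated correlation). They held 0 genes called over all genes and 1 adjusted over the list alone, Clcn1. Interferon response genes were above WT in 24 of 31 members, median 0.07 (camera adjusted p = 0.0171, and adjusted p = 0.604 with an estimated correlation).

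The lists of cellular stress responses had negative medians, again without a gene past the threshold over all genes. The unfolded protein and heat shock genes were below WT in 22 of 22 members, median −0.17 (camera adjusted p = 0.00124, and adjusted p = 0.598 with an estimated correlation). The integrated stress response was below in 17 of 20, median −0.16 (camera adjusted p = 0.0107, and adjusted p = 0.417 with an estimated correlation). The glucocorticoid and fasting list had 13 of 20 members below WT, median −0.21 (camera adjusted p = 0.00105, and adjusted p = 0.417 with an estimated correlation). It had 0 genes called over all genes and 3 adjusted over the list alone: Fkbp5, Zbtb16 and the forkhead factor Foxo3 (−0.52, SE 0.13). The unfolded protein list stood at −0.27, 0.07 and −0.42 in the replicates, and its call was lost at 14 months alone (median −0.08).

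**Figure D4:**
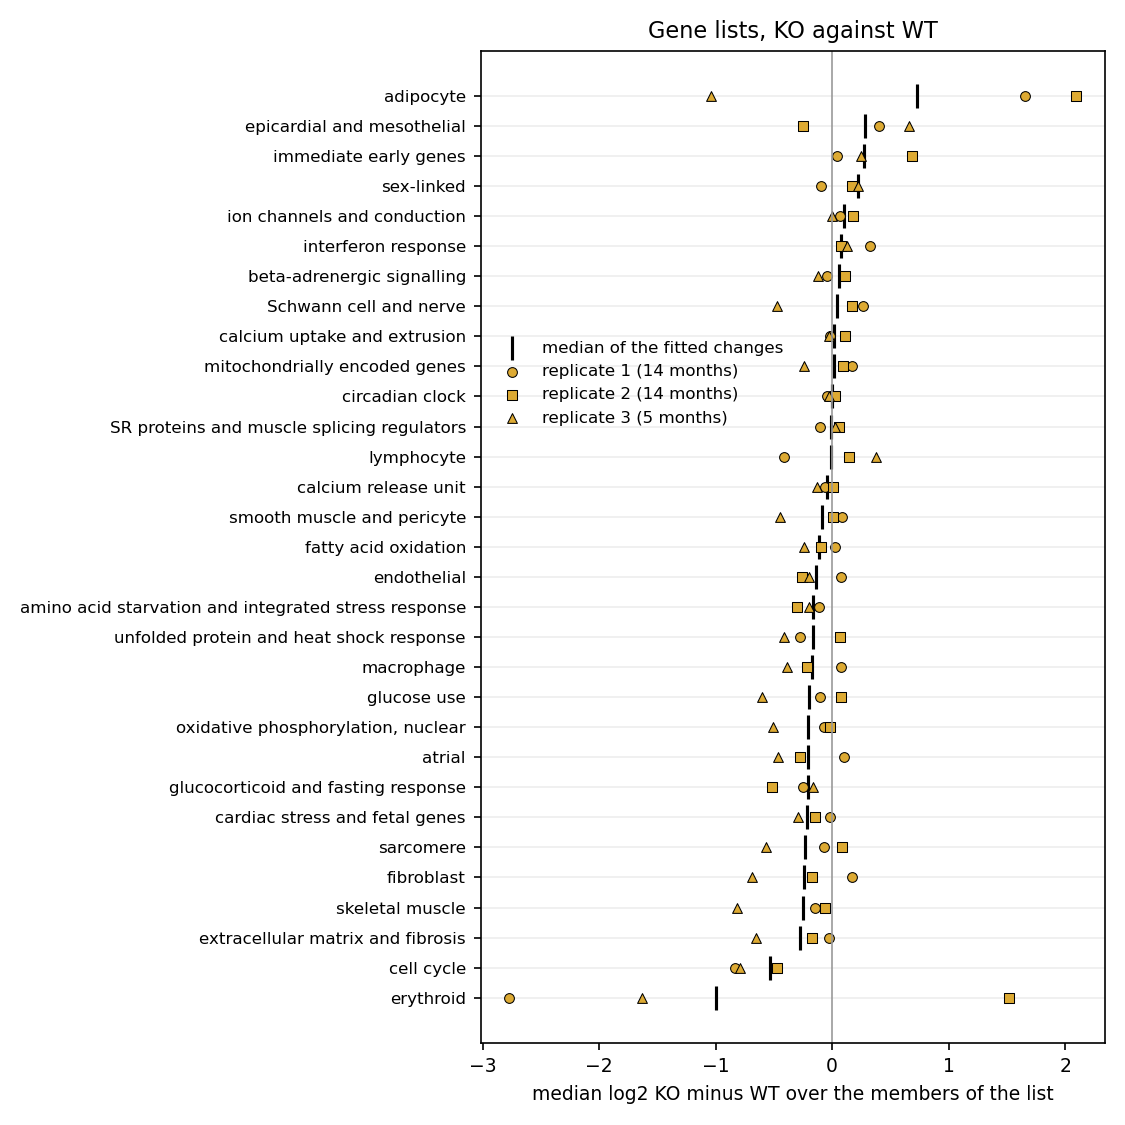
Median log2 KO minus WT over the tested members of each gene list, for each replicate and for the fit with age. Adipocyte and erythroid lists change sign between replicates, while the cell cycle list is negative in all 3.

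Marker genes of blood, atrium and other tissues measure how evenly the hearts were taken. Haemoglobin genes made up 0.316, 0.0337 and 0.0581% of the WT libraries and 0.0469, 0.0935 and 0.0136% of the KO libraries. Hbb-bs, a haemoglobin chain, was at 26444, 2571 and 6482 in WT and 3985, 7350 and 1432 in KO (−1.13 log2). The erythroid list had a median of −0.998 with 8 of 8 below (camera adjusted p = 0.0271, and adjusted p = 0.620 with an estimated correlation) but replicate medians of −2.77, 1.52 and −1.64. Atrial markers had a median of −0.21 with 11 of 18 below (camera adjusted p = 0.0284, and adjusted p = 0.668 with an estimated correlation). Both calls were lost at 14 months alone (medians −0.56 and −0.09). The skeletal muscle list, with Ckm at −0.34, had a median of −0.25 (camera adjusted p = 0.126). The lung list was too small to test, with Hopx at −0.32 and values up to 5283, that of Hopx itself in WT-3. Hopx (1943.63 or more) and Ckm (18323.5 or more) were abundant in every library. Their levels alone therefore do not mark lung or skeletal muscle tissue in these hearts. The circadian list, with Nr1d2 at −0.26, had a median of 0.00 and a mean of −0.04 (camera direction up, adjusted p = 0.990), and its median changed sign under upper-quartile scaling. The sex-linked list, with Ddx3x at 0.17, had a median of 0.22 (camera adjusted p = 0.544).

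The other lists were not called by camera between the genotypes. Beta-adrenergic genes had a median of 0.06 (adjusted p = 0.0735), smooth muscle and pericyte markers −0.09 (adjusted p = 0.127) and epicardial and mesothelial markers 0.28 (adjusted p = 0.318). Mitochondrially encoded genes had a median of 0.02, with a mean of −0.003 (direction up, adjusted p = 0.911). Lymphocyte markers had a median of −0.01 and a mean of 0.03 (direction up, adjusted p = 0.805), and Schwann cell markers a median of 0.04 and a mean of −0.04 (direction down, adjusted p = 0.872). Neutrophil and thymus markers were too few to test, with 4 and 2 members past the filter. Of 31 lists tested, camera called 19 with the preset correlation, 4 up and 15 down, and 0 with an estimated correlation; fry called 0 (smallest adjusted p = 0.0532). Quantile normalization ended the calls of the fatty acid, sarcomere, glucose, stress, atrial, macrophage, erythroid and interferon lists. Removal of length and GC trends ended those of the fatty acid, macrophage, stress, atrial and ion channel lists. Without KO-2 the endothelial, macrophage, integrated stress, atrial, fatty acid, stress, ion channel and interferon calls were lost. In the lists where no count is given above, 0 members passed over all genes and 0 adjusted over the list alone.

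Between 5 and 14 months, 4663 genes passed by limma, 2216 higher and 2447 lower at 5 months (n = 2 and 4 libraries). Trdn was among the higher genes, by 0.70 log2 (SE 0.11, limma adjusted p = 0.00283), and Ryr2 among the lower ones, by −0.49 (SE 0.12, limma adjusted p = 0.0153). Among the 6 higher genes taken by the naming rule, those with an informative name were Pagr1a (chromosome 7, 127015033 to 127017352; 3.44, SE 0.79, limma adjusted p = 0.0133) and Lsm7 (chromosome 10, 80852821 to 80855209). Pagr1a overlaps the predicted gene Gm42742 on the same strand (127015051 to 127021097). In WT-3 Pagr1a was at 99.7 and Gm42742 at 14.8, against 1.06 and 390 in WT-1. How reads were divided between them was not tested, and over the alternatives the limma adjusted p of Pagr1a ran from 0.00455 to 0.133. Lsm7, a component of the spliceosome and of RNA decay complexes, averaged 71.3 (SD 16.3, n = 4) at 14 months and 537 (SD 137, n = 2) at 5 months (2.91, SE 0.22, limma adjusted p = 0.000222). Each age has 1 to 2 mice per genotype and the libraries of an age may share their handling, so age cannot be parted from preparation here. Sex is partly mixed with age as well, since both 5-month mice read as male and replicate 2 of each genotype, at 14 months, as female. With the trends of transcript length and GC content removed in each library 3559 genes passed, with 59.1% of them higher in place of 47.5%, and with a sex term 2650.

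Other large changes with age were in predicted genes and pseudogenes. Gm28661 (chromosome 1, 24614885 to 24615565) was at 0, 0 and 533913 in WT-1 to WT-3 and 0, 18.4 and 368384 in KO-1 to KO-3. Gm28437 (chromosome 1, 24613189 to 24613971) was at 78.1, 0 and 76138 in WT and 0, 0 and 56028 in KO. Both are nuclear copies of mitochondrial sequence: 100% of the 31-base words of Gm28661 occur in mt-Co2 and 100% of those of Gm28437 in mt-Co3. The higher predicted genes were completed by Gm45140 and Gm49339. On the lower side the predicted genes and pseudogenes Gm12918, Rps6-ps4, Rps13-ps2 and Gm49450 were listed at 0 in both 5-month libraries, and Morf4l1-ps1 (0 and 4.46) and Gm4459 (0 and 6.26) were near 0 there.

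The nuclear genes of oxidative phosphorylation were higher at 5 months. Of 45 members 34 rose, 1 fell and 10 did not pass, with a median of 1.04 log2 (camera adjusted p = 2.42e-16, and adjusted p = 0.907 with an estimated correlation). Cox7a1, a subunit of cytochrome c oxidase in heart muscle, went from a mean of 3682 at 14 months to 18852 at 5 months (2.34, SE 0.12). Cox8b (2.43, SE 0.13), Cox6c (2.32, SE 0.13) and the complex I subunit Ndufa2 (2.27, SE 0.14) moved alike, and 36 members passed when adjusted over the list alone. In fatty acid oxidation 15 of 32 rose, 2 fell and 15 did not pass, median 0.42 (camera adjusted p = 0.00470, and adjusted p = 0.907 with an estimated correlation). The electron transfer flavoprotein subunit Etfb rose by 1.62 (SE 0.12) and the fatty acid carrier Fabp3 by 1.17 (SE 0.13), and 19 passed adjusted over the list alone. Among sarcomere genes 11 of 31 rose, 2 fell and 18 did not pass, median 0.39 (camera adjusted p = 0.0306, and adjusted p = 0.942 with an estimated correlation), and 13 passed adjusted over the list alone. Csrp3 (1.51, SE 0.13), the titin cap Tcap (1.40, SE 0.20) and the troponin Tnni3 (1.11, SE 0.19) rose and Mypn fell (−1.19, SE 0.12). Under quantile normalization the fatty acid list lost its call (median 0.24) and the sarcomere median turned to −0.02. The sarcomere call was also lost without WT-1 or without WT-3. The members given as examples in this and the next paragraphs were chosen after their values were seen.

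Matrix, epicardial and early response genes were lower at 5 months. Of 36 extracellular matrix genes 0 rose, 30 fell and 6 did not pass, median −0.85 (camera adjusted p = 7.10e-11, and adjusted p = 0.873 with an estimated correlation), with 31 adjusted over the list alone. The proteoglycan Bgn (−1.68, SE 0.19), the collagens Col1a1 (−1.32, SE 0.18) and Col15a1 (−2.06, SE 0.23) and the matrix glycoprotein Thbs1 (−2.36, SE 0.32) all fell. Of 24 immediate early genes 0 rose, 15 fell and 9 did not pass, median −1.07 (camera adjusted p = 3.94e-07, and adjusted p = 0.907 with an estimated correlation). Among them were the transcription factors Egr1 (−2.85, SE 0.25) and Klf4 (−1.31, SE 0.20), with 19 adjusted over the list alone. Of 12 epicardial and mesothelial markers 0 rose, 7 fell and 5 did not pass, median −1.33 (camera adjusted p = 0.0102, and adjusted p = 0.907 with an estimated correlation). C3 was at −2.04 (SE 0.23), Lrrn4 at −3.30 (SE 0.58) and Wt1 at −1.50 (SE 0.27), and 7 members passed adjusted over the list alone.

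**Figure D5:**
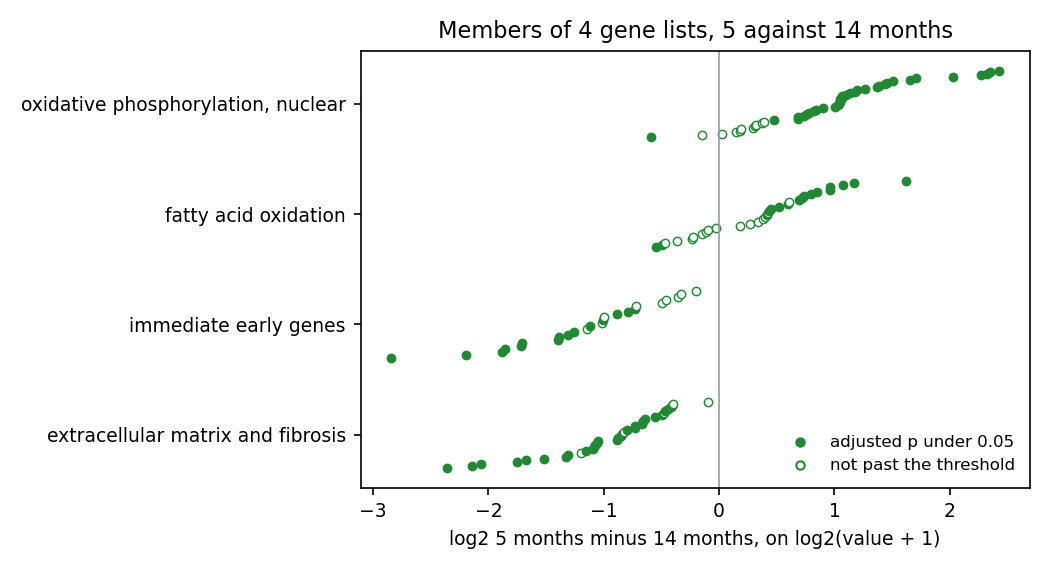
Log2 difference of 5 minus 14 months for each tested member of 4 gene lists, where filled points are genes at an adjusted p under 0.05. Oxidative phosphorylation lies mostly to the right of 0 and the matrix and immediate early lists to the left.

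Among ion channels 2 rose, 14 fell and 22 did not pass, median −0.30 (camera adjusted p = 0.0142, and adjusted p = 0.873 with an estimated correlation), with 16 adjusted over the list alone. The channel beta subunit Scn4b (−1.23, SE 0.15) and the pacemaker channel Hcn4 (−1.35, SE 0.32) fell, while the inward rectifier Kcnj2 rose by 0.61 (SE 0.16). Beta-adrenergic genes had 0 risen, 9 fallen and 17 not passing, median −0.35 (camera adjusted p = 0.0152, and adjusted p = 0.873 with an estimated correlation). The protein kinase A subunit Prkaca was at −0.71 (SE 0.11), with 11 adjusted over the list alone. Both lists lost their call with length and GC trends removed, at medians of −0.02 and −0.16, and without KO-3.

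Lists that camera did not call by age still held changed genes. The calcium release list had 7 risen, 3 fallen and 18 not passing (median 0.16, adjusted p = 0.316, 10 adjusted over the list alone), with Casq2 at 0.30 (limma adjusted p = 0.0823). Calcium uptake and extrusion had 4 risen, 10 fallen and 14 not passing (median −0.31, adjusted p = 0.191, 15 adjusted over the list alone). The stress and fetal genes split, 5 risen, 7 fallen and 15 not passing (median −0.47, adjusted p = 0.251, 13 adjusted over the list alone). In it Nppa rose by 1.42, Fhl2 by 0.70 and Ankrd1 by 0.68. Splicing regulators had 4 risen, 7 fallen and 23 not passing (median 0.03, mean −0.04, direction down, adjusted p = 0.912, 13 adjusted over the list alone), where Qk fell (−0.59). Atrial markers had 6 risen, 5 fallen and 7 not passing (median −0.00, mean 0.14, direction up, adjusted p = 0.760, 12 adjusted over the list alone). In it Myl7 rose by 1.72, Sln by 1.72 and Myl4 by 1.13. Mitochondrially encoded genes had 3 risen (mt-Atp8 by 1.55, mt-Nd3 by 0.58 and mt-Nd4l by 0.53), 1 fallen (mt-Co2, −1.08) and 9 not passing (median −0.14, mean −0.003, direction up, adjusted p = 0.966, 4 adjusted over the list alone). Summed with its nuclear copy Gm28661, mt-Co2 differed by −0.03.

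Fibroblast markers had 3 risen, 7 fallen and 8 not passing (median −0.49, adjusted p = 0.0766, 13 adjusted over the list alone). Smooth muscle and pericyte markers had 1, 6 and 9 (median −0.46, adjusted p = 0.0766, 8 adjusted over the list alone). Endothelial markers had 4, 7 and 7 (median −0.25, adjusted p = 0.251, 11 adjusted over the list alone). The circadian clock had 1 risen, 7 fallen and 11 not passing (median −0.49, adjusted p = 0.407, 9 adjusted over the list alone), where Nr1d2 rose by 0.88. Glucose use had 4, 7 and 13 (median −0.19, adjusted p = 0.749, 13 adjusted over the list alone). The integrated stress response had 0, 5 and 15 (median 0.09, mean −0.06, direction down, adjusted p = 0.826, 5 adjusted over the list alone). The unfolded protein response had 8, 4 and 10 (median 0.22, mean −0.05, direction up, adjusted p = 0.407, 13 adjusted over the list alone). Interferon genes had 4, 4 and 23 (median −0.04, direction up, adjusted p = 0.981, 3 adjusted over the list alone). Macrophage markers had 1, 5 and 17 (median −0.02, adjusted p = 0.784, 6 adjusted over the list alone). The glucocorticoid list had 2, 3 and 15 (median 0.01, adjusted p = 0.975, 5 adjusted over the list alone).

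Adipocyte markers had 0 risen, 1 fallen and 14 not passing (median −0.74, adjusted p = 0.321, 1 adjusted over the list alone). Skeletal muscle markers had 0, 1 and 9 (median 0.28, mean −0.12, direction up, adjusted p = 0.777, 1 adjusted over the list alone). Sex-linked genes had 0, 1 and 7 (median 1.09, adjusted p = 0.826, 0 adjusted over the list alone). No 5-month library read as female, so sex and age are mixed in that median. Cell cycle genes (median 0.07, adjusted p = 0.673), lymphocyte markers (median 0.00, mean −0.09, direction down, adjusted p = 0.912), Schwann cell markers (median −0.38, adjusted p = 0.331) and erythroid genes (median −0.99, adjusted p = 0.321) held 0 called genes over all genes and 0 adjusted over the list alone. Of the genes named as checks of sampling, Hopx rose by 0.77 (0.21 and not past the threshold with length and GC trends removed), and Ckm (0.55), Hbb-bs (−1.13) and Ddx3x (0.04) did not pass. Medians changed sign for macrophage and atrial markers under upper-quartile scaling, for splicing regulators, lymphocyte and glucocorticoid lists under scaling to the total. They also did so for calcium release, splicing, interferon and macrophage lists under quantile normalization, and for glucose, lymphocyte and atrial lists with the length and GC trends removed. Over all alternatives, medians of both signs were also found for adipocyte (−1.60 to 0.62), mitochondrially encoded (−0.83 to 0.01) and skeletal muscle lists (−0.17 to 0.67). Camera called 8 of 31 lists by age, 3 up and 5 down, 0 with an estimated correlation, and fry called 5.

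The difference between the KO and the WT mouse of 5 months departed from that of the 14-month hearts in 287 genes by limma, 122 more positive and 165 more negative at 5 months. It rests on 1 mouse per genotype at 5 months, and the spread on the 14-month hearts alone, so age cannot be parted from these 2 mice. Contractile and metabolic genes made up most of the list members among them. They were 6 of 31 in the sarcomere list, 6 of 45 in oxidative phosphorylation, 5 of 24 in glucose use and 3 of 32 in fatty acid oxidation, all more negative in KO at 5 months. The cardiac actin Actc1 differed by −1.54 log2 between KO and WT at 5 months and by 0.07 at 14 months (interaction −1.62, SE 0.14), and the cardiac myosin Myh6 by −1.28 and −0.02 (interaction −1.26, SE 0.19). The chaperone Cryab differed by −1.40 and −0.06 (interaction −1.34, SE 0.14) and the glycolytic enzyme Gapdh by −1.01 and −0.09 (interaction −0.92, SE 0.13). The ATP synthase subunit Atp5a1 (−0.86, SE 0.14), Cpt2, which imports fatty acids into mitochondria (−1.25, SE 0.16), and Hrc (−1.10, SE 0.14), moved alike. All of these passed an adjusted p of 0.05 by limma, and they were named after their values were seen.

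Of 15 adipocyte markers 4 were called, each above WT at 14 months and below it in the 5-month pair. Pck1 was at 2.19 in KO against WT at 14 months and −1.06 at 5 months (interaction −3.26, SE 0.47), and Car3 at 1.66 and −1.41 (interaction −3.06, SE 0.38). Cfd (−1.78) and Cidea (−1.47) were the other 2. Matrix genes had 3 of 36, namely Ltbp2 (−2.64), Col3a1 (−1.10) and Loxl1 (−1.09), and fibroblast markers Col3a1 and Gsn (−1.29). Outside them Fhl2 (−0.80), Gja1 (−1.20), Gnas (−0.71), Bag3 (−0.89) and Ckm (−0.95) were called, and Srpk1, a kinase of SR proteins, was the list member with a positive interaction (1.11). The 4 genes of smallest p were predicted genes, pseudogenes or retrogenes. They were Vcp-rs (1369, 1378 and 1327 in WT, 0, 0 and 1565 in KO), Gm10039 (733, 1038 and 1089 in WT, 0, 0 and 706 in KO), Eif4a-ps4 (456, 469 and 0 in WT, 630.5, 650 and 182 in KO) and Gm42742 (390, 389 and 14.8 in WT, 399, 364 and 334 in KO). The count was 134 by limma-voom, 764 under scaling to the total (87.4% positive in place of 42.5%), 12 under quantile normalization, 50 with length and GC trends removed, 4 with no filter and as low as 13 with a library left out.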

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

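The test of length and GC trends was written before its result was seen; the tests of pseudogene shares, of genes absent at 5 months and of the mitochondrial copies were chosen after. About 1 in 20 groups of values would stand out by chance: of 43 genes checked, 2 did, where 2.15 were expected. Gm28661 was at 18.4 in KO-2 and at 0 in the other 14-month libraries, and Gm28437 at 78.1 in WT-1 and at 0 in the others of that age. Both are small against the 5-month values of the same genes.

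The genotype difference at 5 months minus that at 14 months was 10.66 log2 in Vcp-rs, 7.05 in Eif4a-ps4, 9.15 in Gm10039 and 4.44 in Gm42742, and it passed the test in 287 genes. The 5-month side is 1 mouse per genotype. Values of 0 in a group set the size of the first 3, and the cause was not tested.

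The count of genes by age could come from transcript length and GC bias between libraries. The Spearman correlation of the age difference was −0.273 with length and −0.291 with GC content (0.268 and −0.0318 for KO against WT). The median fell from 0.35 in the shortest 20% of genes (median length 1404 bases) to −0.21 in the longest (6932). With the trends removed 3559 genes were called, 2750 of them among the 4663, so these trends alone do not account for those. Pseudogenes made up 2.29% of the called genes, but all tested pseudogenes together could reach no more than 7.78%, so this share leaves open how far misassigned reads add to the count. Of 27 genes at 10 or more in all 14-month libraries and at 0 in both 5-month libraries, 17 were processed pseudogenes, against 163 of 13154 genes at 10 or more at 14 months (odds ratio 150, 95% interval 63.8 to 377, Fisher exact p = 1.24e-26), which suggests that reads of copied sequence were assigned differently in the libraries of each age. The sum of mt-Co2 and Gm28661 differed by −0.0279 log2 between ages (95% interval −0.43 to 0.37), while mt-Co2 alone differed by −1.08 (−1.46 to −0.70), which fits mitochondrial reads counted for the nuclear copy at 5 months. No such drop was seen in mt-Co3, at 0.11 alone (−0.26 to 0.47) and 0.21 with Gm28437 (−0.16 to 0.57). Gm28437 was small beside mt-Co3 (56028 against 760622 in KO-3), so that pair cannot decide.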

How the results depend on the processing

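Tests beyond those fixed with the design were chosen after the data were seen. They were total and quantile scaling, upper-quartile scaling of the lists, trend removal, pseudocounts, removal of pseudogenes, 14-month lists and the block with estimated correlation. For KO against WT the count was 0 in all settings but the 14-month libraries alone (14) and the left-out libraries (0 to 5; 1 without WT-2, 5 without WT-3 and 5 without KO-3). With the replicate block, 0 genes passed (583 at unadjusted p under 0.05), Trdn was −0.71 with an adjusted p = 0.886, 19 lists were called and no other call changed. At 14 months alone the estimate of Trdn was about the same (−0.71) with a smaller limma adjusted p = 0.0476 (range 0.0476 to 1.00). Its estimate ran from −0.84 with trends removed to −0.60 with quantile normalization. The 10 genes of smallest p kept their sign in 229 of 229 checks, of which 8 had an adjusted p under 0.05. As these genes were chosen in the same libraries, the kept sign says little about stability. The 26 named genes other than Trdn kept their sign in 568 of 596 checks, a count that again takes in the other genes of smallest p.

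The age count moved from 4663 to 2650 with a sex term (2593 shared) and lay between 3246 and 4533 with a library left out. It was 5962 at a threshold of 0.10, 4515 by limma-voom and 4093 with scaling to the total (39.7% higher in place of 47.5%). The interaction count moved from 287 to 1112 at a threshold of 0.10, 134 by limma-voom, 4 without a filter, 764 with scaling to the total (87.4% positive in place of 42.5%; median shift of all genes 0.24 in place of −0.05), 12 with quantile normalization (58.3% positive) and 50 with trends removed (36.0%). With a library left out it lay between 13 and 234: 15 without WT-1, 13 without WT-2, 234 without KO-1 and 222 without KO-2. Without a 5-month library it could not be fitted.

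The KO list count moved from 19 to 0 with an estimated correlation, 0 with fry, 0 with the block and an estimated correlation, 12 with quantile normalization and 10 at 14 months alone, and lay between 10 and 18 with a library left out. It was 11 without KO-2, 10 without WT-3 and 10 without KO-3. The age list count moved from 8 to 0 with an estimated correlation and 5 with fry, and lay between 6 and 11 with a library left out. The sarcomere list by age reversed with quantile normalization, from 0.39 to −0.0240. Over all alternatives the age median of nuclear oxidative phosphorylation ran from 0.66 to 1.23 and that of extracellular matrix from −1.22 to −0.52. The count-based Wald test was not run, and the causes of these moves were not tested.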

Other observations

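Of the tests below, the splits of the libraries were written before their result was seen and all others were chosen after. The values of adipocyte genes varied between the replicates. Ucp1, the uncoupling protein of brown fat, was at 108 and 8.71 in WT-1 and WT-2 and 465 and 788 in KO-1 and KO-2, but at 26.5 in WT-3 and 4.26 in KO-3. Adipoq, an adipocyte hormone, was at 65.5 and 53.3, 133 and 246, 137 and 63.3 in the same order. Neither passed between KO and WT (limma adjusted p = 0.795 and 0.752) or in the interaction (limma adjusted p = 0.2495 and 0.0592). Sln, the sarcolipin that binds the calcium pump, was at 1047, 797 and 3198 in WT and 919, 628 and 2376 in KO, so its values at 5 months were far above those at 14 months in both genotypes.

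The counts were also taken for the other splits of the 6 libraries into 3 and 3. As the real count of genes is 0, 10 of 10 splits give as many by construction, with 2 as the highest of the others, so this count tests nothing. For lists, 1 of 10 gave as many as the real one (19); the highest other was 17 and the lowest 7. Among the 4 splits that part all 3 same-number pairs, the highest other gave 11 lists and 0 genes, and at unadjusted p under 0.05 the real split had 841 genes and the highest other 742. With 10 splits no share under 0.05 can be reached.

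Gm47845 was lower in KO than in WT in 3 of 3 pairs. Its reads might follow those of the Trdn transcript around it, but the upper 95% bound of its log2 fold change was −1.22, below the −0.71 of Trdn. As the gene was picked for its low values, all KO values are near 0 and its adjusted p is 0.745, this account stays open. It could also rest on a single library, but with each library left out it stayed between −2.92 and −2.13. In approximate reads the KO total was 11 against 75, or 14.2% of WT (6.82 to 27.0% from counting error alone). As a hypothesis, its reads may come from RNA of the region that the knockout altered, since the nearer end of the antisense gene D830005E20Rik, its 3' end, lies 10712 bases away. Reads by strand would test this and were not used here.

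Fkbp5 and Zbtb16 could be lower in KO because hearts were taken at another time of day. The contrast of clock genes high at opposite times moved by 0.96, 1.01 and 0.25 log2 in replicates 1, 2 and 3, with the smallest between the bounds set for either answer, so time of day is left open. A weaker glucocorticoid response might lower them too: the 9 other direct targets had a median of −0.246, with 3 higher and 6 lower in KO, but medians of −0.36, 0.34 and −0.24 in the replicates, which leaves this open as well. The hypothesis of a change in stress hormone could be tested with corticosterone and hearts taken at a fixed hour.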
